A study of Mus musculus with 8 samples.

How the data were processed

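The series holds 8 RNA-seq libraries of macrophages sorted from the colon of C57BL/6 mice kept specific pathogen free, 4 from mice of 8 days of age and 4 from mice of 14 days. Per the labels' protocols, 300 to 3000 sorted cells were collected per sample in lysis buffer, cDNA was made and amplified with the SMART-seq v4 Ultra Low Input kit, and 50 bp single-end reads were sequenced on a NextSeq500. This kit amplifies full-length cDNA without molecular identifiers and does not mark the strand. Per the submitters' processing notes, STAR, HTSeq, Partek 10 and DESeq2 were used with the mouse build GRCm38 (mm10), with no role or order given for each tool. The markers used for sorting and the gene annotation are not given in the sources used here.

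The deposited values are TPM (transcripts per 1000000, a share of reads corrected for transcript length), in 1 table of 25267 gene symbols with 1 column per library. Each column sums to 1000000. No mitochondrially encoded gene is listed under an mt- symbol (0 symbols). Because TPM values are shares, a higher share of a few transcripts lowers the values of all others. TPM does not state the read depth, but after each library's values were divided by a factor for what 1 read is worth there (1.0 to 4.83 relative to the smallest), each gene's values were whole multiples of a unit of that gene, so whole reads could be recovered: for 14343 of 14343 genes above 0 in at least 2 libraries (100%), all values lay within 1e-05 of a whole read (largest distance 1.7e-09). Another 1792 genes were above 0 in 1 library only and gave no read number, and 9132 genes were at 0 in every library. On simulated TPM of 3000 genes, 99.68% of the genes seen in at least 3 libraries were recovered exactly. The recovered depth ran from 8237379 to 31007728 reads per library. To compare libraries at equal depth, the expected number of genes with at least 10 reads was computed after binomial thinning of each library to 8237379 reads. Amplified reads are not independent molecules, so floors and read numbers cover counting error only. For a gene with no read at day 8, the floor is the TPM that 3 reads would give in a day 8 library, taking the library with the highest such value.

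Groups were taken from the sample titles and ages. The main test, fixed before the data were examined, was limma 3.58.1 (lmFit and eBayes with trend, R 4.3.3) on log2(TPM + 1), two-sided, with age as the only term, over the 8621 genes with a TPM of at least 1 in at least 4 of the 8 libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are day 14 over day 8 on the log2(TPM + 1) scale, which understates the change of low genes. Count models were planned only for a table of counts and were not used for the main test. Voom on the recovered reads was added later as an alternative. The labels do not say whether the libraries of a group came from separate animals or litters, so p-values measure the spread between these libraries, which may be partly technical.

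In all, 33 gene lists were fixed before the data were examined: 19 macrophage and tissue programmes, 2 lists that respond to cell handling (immediate-early genes, heat shock and unfolded protein genes) and 12 lists of markers of other cells. The programmes were monocyte-derived macrophage genes, self-maintaining resident macrophage genes, colon macrophage core genes, MHC class II and costimulation, MHC class I presentation, CD1d lipid presentation and signals to iNKT cells, mitosis, DNA replication, interferon response, inflammatory cytokines and chemokines, microbial sensing, lysosome and efferocytosis, cholesterol synthesis, lipid storage and efflux, iron and heme handling, oxidative phosphorylation, glycolysis, postnatally silenced growth genes, and growth and repair factors. The cell lists covered epithelial, T, B and plasma, NK and innate lymphoid, neutrophil, eosinophil, dendritic, mast, fibroblast and muscle, endothelial, neuron and glia, and erythroid markers. The 26 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists, with camera at an estimated correlation and fry beside it. Added after seeing the data were 22 further fibroblast and muscle markers and 21 further epithelial markers, none in the fixed lists and written down before their own levels were seen, to test which cells the libraries held. Each library's list level is the mean log2(TPM + 1) over the members in the table.

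Genes are named by a rule fixed in advance. It takes the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a mean of at least 5 TPM and no overlap between groups, filled by the smallest p where fewer pass. It adds the members of each list with the smallest p, of which 2 are used here and 4 for the monocyte-derived, resident and mitosis lists, and 16 genes named in any case. Predicted, Rik and LOC symbols, Xist and Y-linked genes are left out of the first part. Coordinates are from the RefSeq gene table of GRCm38.p6, in which 25118 of the 25267 symbols matched once.

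The test was checked on simulated data for this comparison. With counts drawn at the spread of the day 14 libraries (8497 genes), it recovered 50% of genes changed by log2 1, 83.6% at log2 2 and 93.7% at log2 3, with 0.12% of unchanged genes called. In a second simulation (8621 genes), each group's mean was removed from the real values, which kept their spread, and known changes were added. The test then recovered 0%, 5.97% and 18.2%. An unchanged gene differed by exactly 0 between groups there, so the 0% of unchanged genes called was fixed in advance. The added changes carried no sampling error, so these shares show only how far the spread limits the calls. Alternatives covered the pseudocount, the filter, quantile normalization, median alignment, removal of the 104 ribosomal protein genes, the variance model, array weights, a replicate block, leaving out each library, an exact permutation test and a fold threshold. Chosen after seeing the data were a fit without day 8 replicates 1 to 3 and voom on the recovered reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.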

Results

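Macrophages were sorted from the colon of mice at 8 and at 14 days of age, and their polyadenylated transcripts were sequenced in 4 libraries per age. The series concerns macrophages of embryonic origin in early life and their role in setting the number of iNKT cells, T cells that recognise lipids on CD1d. The comparison of day 14 with day 8 asks how the macrophage transcriptome differed between these ages. The day 8 libraries held 19526516, 8237379, 13136893 and 11496675 recovered reads (replicates 1 to 4), and the day 14 libraries 22981179, 31007728, 25205653 and 29929514. Thinned to 8237379 reads, the day 14 libraries had between 10824 and 11063 genes with at least 10 reads. Day 8 replicate 4 had 10343 such genes, while day 8 replicates 1, 2 and 3 had 6698, 7325 and 4708.

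**Figure D1:**
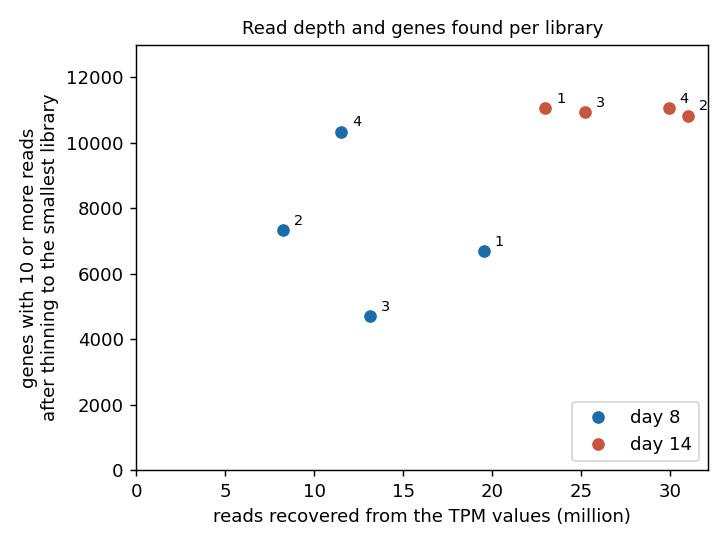
Genes with at least 10 reads after thinning every library to 8237379 reads (y axis) against the reads recovered from the TPM values (x axis, in units of 1000000 reads), with libraries as points numbered by replicate and coloured by age. Day 8 replicates 1 to 3 lie at 4708 to 7325 genes and the other libraries at 10343 or more.

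The day 8 libraries differed from each other in their content of macrophage transcripts. Csf1r, the receptor that macrophages need to survive, stood at 0.0729, 6.97, 0.0615 and 216.7 TPM in day 8 replicates 1 to 4, and between 330.6 and 467.3 TPM at day 14. Those day 8 values rest on 5, 196, 3 and 11610 reads. The complement gene C1qa stood at 1.91, 320.1, 0.894 and 7194 TPM at day 8 and between 8759 and 9540 TPM at day 14. The chemokine receptor gene Cx3cr1 stood at 0.019, 0, 0.0267 and 122.4 TPM at day 8 and between 148.7 and 232.9 TPM at day 14. Over the 24 colon macrophage core genes, the mean log2(TPM + 1) was 2.65, 3.93, 2.34 and 7.77 in the day 8 libraries and 8.03 to 8.18 at day 14. Fibroblast and muscle markers went the other way, at 8.25, 8.14, 8.14 and 2.17 at day 8 and 2.93 to 3.65 at day 14. Dcn, which encodes the matrix proteoglycan decorin, was at 3892, 3006, 2632 and 5.02 TPM at day 8, against 7.58 to 19.8 TPM at day 14. Endothelial markers were high in day 8 replicates 1 and 2 (4.83 and 3.82) and low in replicates 3 and 4 (0.01 and 0.57). Across all genes, Spearman's rho between day 8 replicate 4 and the day 14 libraries was 0.901 to 0.916. Among the day 8 libraries it was 0.579 to 0.696, genes not being independent replicates.

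**Figure D2:**
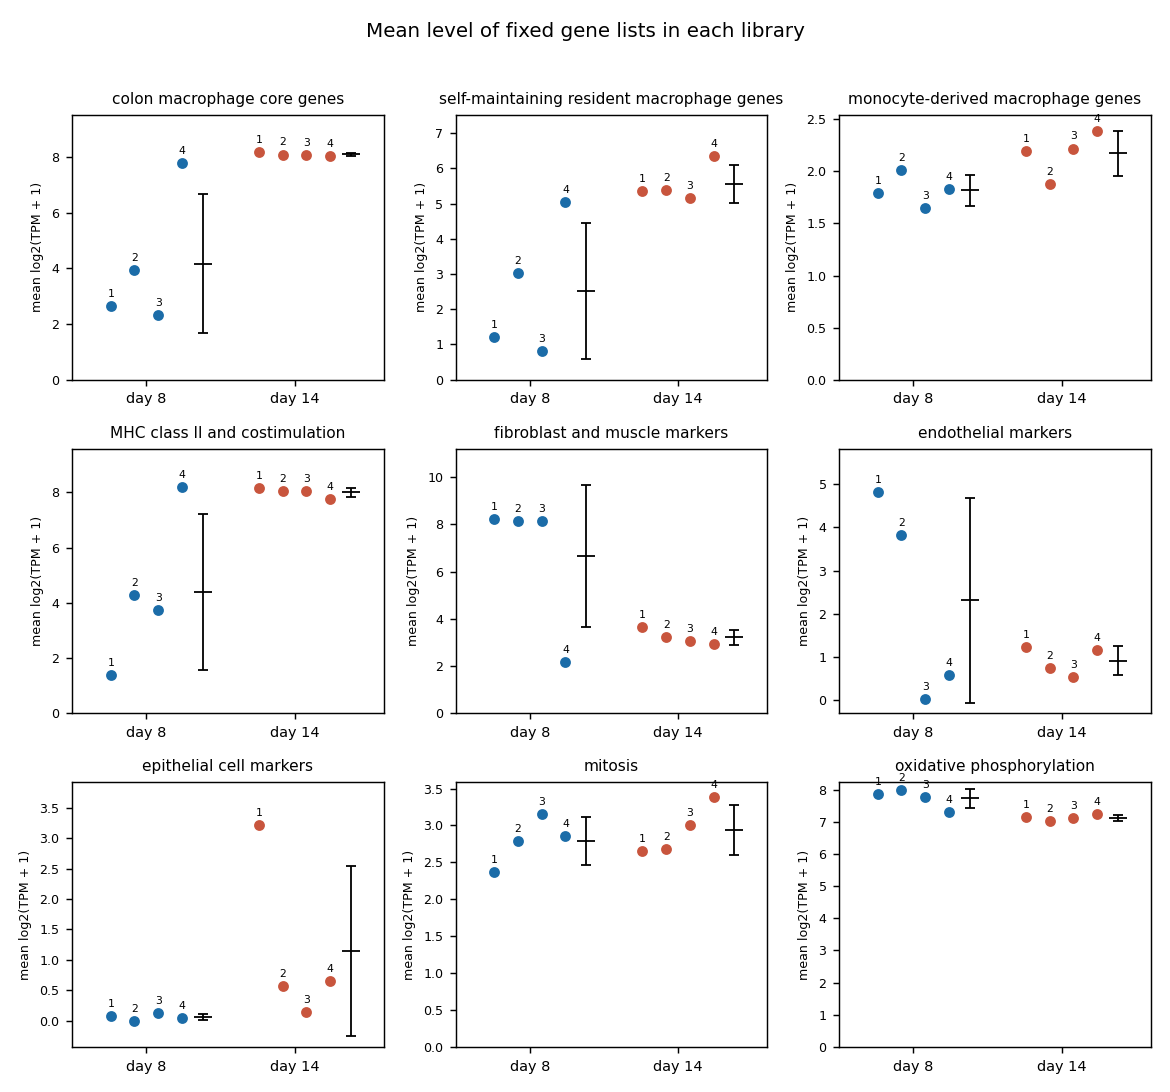
Mean log2(TPM + 1) of 9 fixed gene lists in each library, with day 8 in blue, day 14 in red, points numbered by replicate and bars for the mean and SD of each group of 4. Day 8 replicates 1 to 3 lie at 2.34 to 3.93 for the colon macrophage core genes and at 8.14 to 8.25 for fibroblast and muscle markers, where day 8 replicate 4 lies at 7.77 and 2.17.

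Cd209f, a C-type lectin gene of resident macrophages, rose from 28.1 ± 56.3 TPM at day 8 to 560.6 ± 201.3 TPM at day 14 (SD, n = 4), a log2 fold change of 7.37 (SE 1.45, limma adjusted p = 0.0482). It had no read in day 8 replicates 1 to 3 and 701 reads in replicate 4. Cirbp, which encodes a cold-inducible RNA-binding protein, fell from 402.5 ± 207.1 TPM to 67.2 ± 14.7 TPM (n = 4, log2 fold change -2.44, SE 0.43, limma adjusted p = 0.0357). It was higher in each of the 4 day 8 libraries (226 to 651.2 TPM) than in any day 14 library (53.2 to 87.9 TPM). Tfrc, the transferrin receptor gene, rose from 0.503 ± 0.796 to 6.28 ± 1.75 TPM (n = 4, log2 fold change 2.38, SE 0.47, limma adjusted p = 0.0487). Its day 8 values were 0.312, 0, 0.0219 and 1.68 TPM, and without day 8 replicates 1 to 3 it did not pass (log2 fold change 1.42, limma adjusted p = 0.109). Cd209f lies on chromosome 8 (4102784 to 4105838), Cirbp on chromosome 10 (80165990 to 80172786) and Tfrc on chromosome 16 (32608896 to 32632794) of GRCm38.

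In all, 126 of 8621 genes passed the test, 125 higher and 1 lower at day 14. Of the 125, 99 were under 1 TPM in all 4 day 8 libraries, 33 had no read at day 8, and the median of their mean day 14 levels was 3.37 TPM. Hars2, a mitochondrial histidine tRNA synthetase gene, rose by log2 3.85 (SE 0.75, limma adjusted p = 0.0482). Castor1, which encodes an arginine sensor of the mTORC1 pathway, rose by log2 3.40 and Chp2 by 3.30, and each was under 4 TPM in every day 8 library. Retnlg, a resistin-like gene known from neutrophils, had no read at day 8 and 15.4 ± 6.96 TPM at day 14 (SD, n = 4), at least 10.7-fold above the floor of 3 reads. Snora28 rose by log2 5.63 over the 4 day 8 libraries, of which 3 had no read and replicate 4 had 27.6 TPM, to 114.5 ± 18.7 TPM at day 14 (n = 4). Against replicate 4 alone the log2 fold change was 2.0. This small RNA, like Mir132, Mir7688, Snord37 and Mir6992, can share reads with a gene it lies in, so its value is uncertain. The last 4 passed the test on 2 to 15 reads per day 14 library, and the floor of 3 reads at day 8 lay above their day 14 means, so no fold is given. The groups did not overlap for 1458 genes (16.9%), where chance gives 2.86% on average. Genes varied together, with day 8 replicates 1 to 3 apart in content, so this share is not a test. Leaving out day 8 replicate 1, 2 or 3, or day 14 replicate 1, 3 or 4, left 0 genes past the limma threshold (2189, 2440, 2224, 1872, 1865 and 1833 at an unadjusted p under 0.05). Without day 14 replicate 2 there were 24 genes, and without day 8 replicate 4 there were 3254.

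The 9 further genes of lower level at day 14 with the smallest p did not pass. They were Anxa1, Ubb, Nnat, Eif5a, Aldoa, Fam136a, Lgals1, Ndn and Tmed1. Ndn, an imprinted gene of growth arrest, had 1415 ± 923 TPM at day 8 and 22.9 ± 13.8 TPM at day 14 (n = 4, limma adjusted p = 0.0711), with 39.0 TPM in day 8 replicate 4. Anxa1, whose product dampens inflammation, had 222.8 ± 113.3 TPM at day 8 and 27.4 ± 11.4 TPM at day 14 (n = 4, limma adjusted p = 0.0590). The glycolytic gene Aldoa had 1676 ± 501.6 and 698.4 ± 62.9 TPM (n = 4, limma adjusted p = 0.0705). In day 8 replicate 4, Anxa1 was at 60.1 and Aldoa at 960.8 TPM. Without day 8 replicates 1 to 3 their log2 fold changes went from -2.83 to -1.20 and from -1.21 to -0.46. At an unadjusted limma p under 0.05, 1868 genes were higher and 660 lower at day 14. The median log2 fold change of all genes tested was 0.53, and -0.35 with library medians aligned. Aligning medians lowers every log2 fold change by the same amount. That amount was set mostly by day 8 replicate 3, whose median log2(TPM + 1) was 0.12, against 3.17 to 3.61 in the other libraries. A change of sign with aligned medians therefore follows from that shift and is no separate evidence on a list. No gene passed with quantile normalization or aligned medians (0 each by limma, with 2144 and 1035 genes at an unadjusted p under 0.05, of which 1029 and 416 were higher).

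Among the gene lists, 13 of 26 passed camera at the preset correlation, and 0 passed with an estimated correlation. The colon macrophage core genes rose as a list (median log2 fold change 3.75, 24 genes tested, camera adjusted p = 3.01e-06). None passed on its own over all genes, and 21 passed adjusted over the list alone, 20 of them higher. The lower one, Cd63, named after its values were seen, was at 1658 ± 465.6 TPM at day 8 and 918.8 ± 79.6 TPM at day 14 (SD, n = 4). Runx3, a transcription factor gene, was at 0.362 ± 0.724 TPM at day 8 and 4.31 ± 1.26 TPM at day 14 (n = 4, limma adjusted p = 0.0501). Itgam, the CD11b integrin gene, was at 0.97 ± 1.94 and 9.41 ± 1.01 TPM (n = 4, limma adjusted p = 0.0671). Adgre1, which encodes the F4/80 antigen, was at 12.3 ± 19.1 and 78.4 ± 8.52 TPM (n = 4, limma adjusted p = 0.0764). For the core genes camera's adjusted p was 0.423 with an estimated correlation. Their mean was lowest in day 8 replicates 1 to 3, and in day 8 replicate 4 (7.77) it also lay below that of every day 14 library (8.03 to 8.18). Without those 3 libraries the median was 0.35 (camera adjusted p = 0.475).

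Self-maintaining resident macrophage genes rose as a list, with a median log2 fold change of 3.45 over 16 genes (camera adjusted p = 0.000592). Of these, Cd209f passed over all genes and 11 passed adjusted over the list alone, all higher. Cd209g, a neighbour and close relative of Cd209f that can share reads with it, was at 7.55 ± 15.1 TPM at day 8 and 75.6 ± 30.6 TPM at day 14 (n = 4, limma adjusted p = 0.0673). Cd4, carried by long-lived gut macrophages, was at 0.0159, 2.05, 0 and 10.7 TPM at day 8 and 17.8 to 36.3 TPM at day 14 (limma adjusted p = 0.0764). The haemoglobin scavenger receptor gene Cd163 was listed at 0, 0, 0 and 4.72 TPM at day 8 and at 3.99 to 22.2 TPM at day 14 (limma adjusted p = 0.0818). Timd4, a phosphatidylserine receptor of resident macrophages, had no read in day 8 replicates 1 to 3, 12.4 TPM in replicate 4 and 6.63 to 11.8 TPM at day 14 (limma adjusted p = 0.134). Mrc1 was at 8.07 ± 10.6 and 33.3 ± 7.33 TPM (n = 4, limma adjusted p = 0.108), and Lyve1 at 19.1 ± 15.1 and 41.9 ± 41.1 TPM (n = 4, limma adjusted p = 0.449). The list's camera adjusted p was 0.423 with an estimated correlation, and 0.378 without day 8 replicates 1 to 3, where the median was 0.53.

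Monocyte-derived macrophage genes did not pass (median log2 fold change 1.79 over 8 genes, camera adjusted p = 0.593), and members lay on both sides. The median was 0.21 with quantile normalization and 0.91 with aligned medians, and the list passed fry (adjusted p = 0.0402), which does not compare it with other genes. Of the 8 genes, 5 were higher and 2 lower at an unadjusted p under 0.05, and adjusted over the list alone 7 passed, 5 of them higher. Ccr2, the receptor by which monocytes leave the bone marrow, had no read in day 8 replicates 1 to 3, 7.96 TPM in replicate 4 and 4.27 to 13.4 TPM at day 14 (limma adjusted p = 0.0996). Ly6c2, a marker of inflammatory monocytes, was at 0.0979, 0, 0.275 and 6.76 TPM at day 8 and 4.49 to 10.6 TPM at day 14 (limma adjusted p = 0.104). Ms4a4c and Itgal followed the same split, at 8.72 and 4.44 TPM in day 8 replicate 4 and at most 0.027 TPM in replicates 1 to 3. Plac8 was at 93.0, 149.5, 238 and 6.30 TPM at day 8 and 3.56 to 10.5 TPM at day 14 (limma adjusted p = 0.0963). S100a6, named after its values were seen, was at 1374, 1493, 1918 and 46.4 TPM and at 63.0 to 151.2 TPM (limma adjusted p = 0.115). Neither passed, and without day 8 replicates 1 to 3 their log2 fold changes turned to 0.15 and 0.86.

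**Figure D3:**
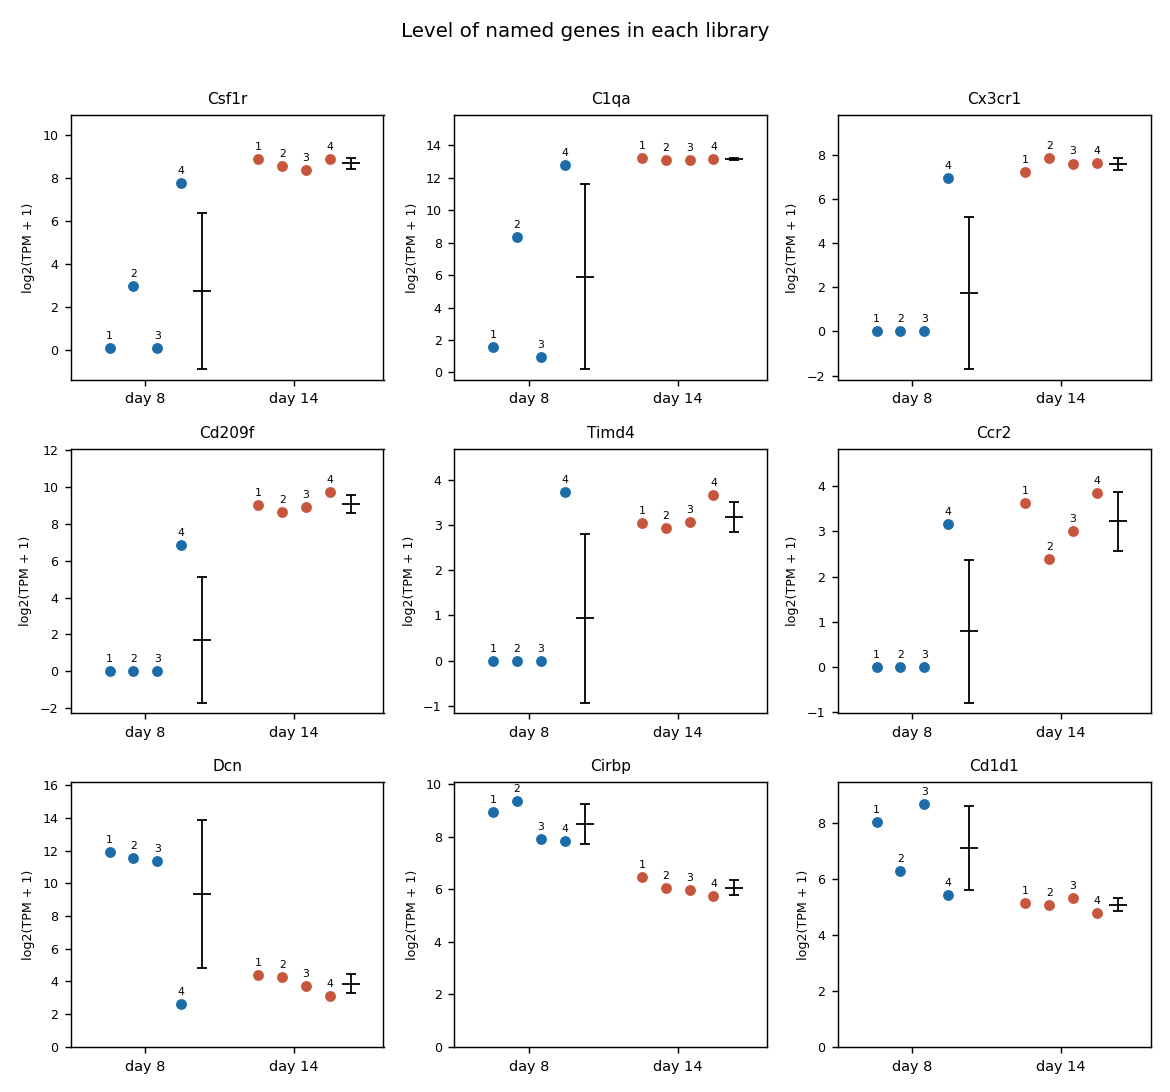
Level of 9 named genes in each library as log2(TPM + 1), with day 8 in blue, day 14 in red, points numbered by replicate and bars for the mean and SD of each group of 4. For Csf1r, C1qa, Cx3cr1, Cd209f, Timd4 and Ccr2, day 8 replicate 4 lies far above replicates 1 to 3, and for Dcn far below them, while Cirbp lies at 226 to 651.2 TPM in all 4 day 8 libraries and at 53.2 to 87.9 TPM at day 14.

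Mitosis genes did not pass (median log2 fold change 0.25, -0.51 with quantile normalization and -0.63 with aligned medians, mean 0.10, 18 genes, camera adjusted p = 0.295), and camera placed the list lower than other genes while its median was above 0. The spindle checkpoint gene Cdc20 was at 206 ± 126.5 TPM at day 8 and 36.9 ± 5.07 TPM at day 14 (n = 4, limma adjusted p = 0.0893). Ube2c was at 379.4 ± 319.1 and 86.4 ± 12.1 TPM (n = 4, limma adjusted p = 0.121), and Cdk1 at 47.1 ± 24.4 and 25.0 ± 2.96 TPM (n = 4, limma adjusted p = 0.340). In day 8 replicate 4, Cdc20, Ube2c and Cdk1 were at 37.7, 82.3 and 25.7 TPM. Without day 8 replicates 1 to 3 their log2 fold changes were -0.039, 0.058 and -0.043. Mki67, the proliferation marker, had no read in day 8 replicates 1 to 3, 2.23 TPM in replicate 4 and 0.952 to 3.13 TPM at day 14. DNA replication genes did not pass either (median 1.14, camera adjusted p = 0.289). They passed, higher, with quantile normalization (median 0.73, camera adjusted p = 0.023), and had a median of 0.26 with aligned medians (camera adjusted p = 0.139). Among them were Cdc6 at 0.421 ± 0.843 and 3.45 ± 1.47 TPM and Mcm4 at 4.94 ± 5.72 and 20.2 ± 4.92 TPM (SD, n = 4).

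For lipid presentation to iNKT cells, Cd1d1 encodes the presenting molecule and Cxcl16 the ligand of their receptor CXCR6. Cd1d1 was at 266, 77.6, 407.9 and 42.2 TPM at day 8 and 26.5 to 39.1 TPM at day 14 (log2 fold change -2.03, SE 0.70, limma adjusted p = 0.104). Cxcl16 was at 251.8, 86.6, 0.0936 and 919.8 TPM at day 8 and 845.5 to 1212 TPM at day 14 (log2 fold change 3.95, SE 1.73, limma adjusted p = 0.165). Psap, the precursor of saposins, was at 45.1 ± 21.9 and 168.3 ± 45.5 TPM (n = 4, limma adjusted p = 0.0711). The SLAM receptor gene Slamf6 was at 1.73 ± 3.46 and 9.09 ± 1.35 TPM (n = 4, limma adjusted p = 0.0831). The list of CD1d lipid presentation and iNKT cell signals did not pass (median 1.44 over 13 genes, camera adjusted p = 0.586). Its median was 0.71 with quantile normalization and 0.56 with aligned medians (camera adjusted p = 0.0628 and 0.323). With day 8 replicates 1 to 3 left out, the log2 fold change was -0.34 for Cd1d1 (limma adjusted p = 0.45), 0.21 for Cxcl16 (0.573), 1.17 for Psap (0.143) and 0.34 for Slamf6 (0.516), and the list's median was 0.05 (camera adjusted p = 0.611).

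Antigen presentation and inflammatory lists rose with the macrophage core genes. MHC class II and costimulation had a median log2 fold change of 3.56 (13 genes, camera adjusted p = 0.0021), with H2-Ab1 at 6.26, 1081, 1885 and 9311 TPM at day 8 and 5137 to 8982 TPM at day 14. Its members Cd86 (11 ± 19.7 and 47.1 ± 5.37 TPM, n = 4) and Ctss did not pass alone. MHC class I presentation had a median of 1.67 (12 genes, camera adjusted p = 0.0469), with B2m at 2432 ± 2899 and 7094 ± 764.3 TPM and H2-K1 at 729.5 ± 1128 and 2630 ± 947.1 TPM (SD, n = 4). Inflammatory cytokines and chemokines had a median of 3.64 (21 genes, camera adjusted p = 0.00196). Il1b was at 0.511, 0.139, 0.16 and 1444 TPM at day 8 and 1219 to 2360 TPM at day 14, and Ccl8 at 6.80 ± 13.6 and 104.9 ± 58.1 TPM (SD, n = 4). Microbial sensing genes had a median of 2.85 (17 genes, camera adjusted p = 0.000187), with Tlr2 at 62.0 ± 123.8 and 558 ± 41.5 TPM and Tlr8 at 0.589 ± 1.16 and 6.65 ± 1.46 TPM. Interferon response genes had a median of 2.5 (20 genes, camera adjusted p = 0.00383), with Oasl2 at 0.760 ± 1.49 and 13.1 ± 4.60 TPM and Ifit1 at 0.942 ± 1.88 and 8.17 ± 3.23 TPM. No member of these 5 lists passed over all genes. Adjusted over the list alone, 4, 3, 11, 12 and 6 members passed, in the order given, all higher except 1 of the 11 inflammatory genes. That gene, Il6, named after its values were seen, was at 73.0, 98.7, 690.9 and 0 TPM at day 8 and 0 to 2.45 TPM at day 14 (log2 fold change -4.79, limma adjusted p = 0.111 over all genes). The median was 1.74 with quantile normalization and 1.62 with aligned medians for the interferon list, and 1.66 and 0.79 for MHC class I. With an estimated correlation the adjusted p of each of these lists was 0.423. Without day 8 replicates 1 to 3 the median was -0.22 for MHC class II (camera direction lower), so its rise turned against day 8 replicate 4 alone. For MHC class I the median was 0.12. It was 0.41 for inflammatory cytokines and chemokines, 0.35 for microbial sensing and 0.0047 for the interferon response. Without day 8 replicate 4 the MHC class I list did not pass (camera adjusted p = 0.105).

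Lysosome and efferocytosis genes rose as a list (median log2 fold change 1.46, 20 genes, camera adjusted p = 0.00196), as did iron and heme handling genes (1.62, 12 genes, camera adjusted p = 0.0021). Grn, which encodes progranulin, was at 945.3 ± 706.9 and 2585 ± 206.6 TPM, and Spic, a transcription factor gene of iron-recycling macrophages, at 16 ± 32.1 and 106.8 ± 30.4 TPM (SD, n = 4). Both lists had 6 members past the threshold adjusted over the list alone, and both had an adjusted p of 0.423 with an estimated correlation. Without day 8 replicates 1 to 3 their medians fell to 0.34 and 0.29. With library medians aligned their medians were 0.58 and 0.74 (camera adjusted p = 0.0264 and 0.00238). Lists that did not pass included lipid storage and efflux (median 0.76, and -0.12 with library medians aligned, camera adjusted p = 0.329), with the cholesterol exporters Abca1 at 0.877 ± 1.25 and 6.34 ± 1.18 TPM and Abcg1 at 0.254 ± 0.296 and 1.6 ± 0.0739 TPM. Growth and repair factors did not pass (median 0.71, and -0.17 with library medians aligned, camera direction lower, camera adjusted p = 0.952), with Osm at 46.3 ± 92.5 and 316.5 ± 85.9 TPM and Pdgfb at 1.80 ± 3.58 and 11.1 ± 2.36 TPM.

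Oxidative phosphorylation genes fell as a list (median log2 fold change -0.62, 25 genes, camera adjusted p = 1.91e-06). None passed over all genes, and 7 passed adjusted over the list alone, all lower. The mean of the list was 7.31 to 7.98 in the 4 day 8 libraries and 7.03 to 7.26 at day 14, without overlap. The ATP synthase genes Atp5b (2612 ± 1100 and 1039 ± 81.8 TPM) and Atp5c1 (228.9 ± 87.1 and 84.1 ± 4.16 TPM) had the smallest p (n = 4, limma adjusted p = 0.0831 each). The list stayed lower without day 8 replicates 1 to 3 (median -0.19, camera adjusted p = 2.78e-05, and adjusted p = 0.651 with an estimated correlation). With all libraries its adjusted p was 0.419 with an estimated correlation, and 0.213 with quantile normalization, where its median was -0.30, against -1.50 with aligned medians (camera adjusted p = 7.02e-05). Cholesterol synthesis genes fell as a list too (median -0.45, 20 genes, camera adjusted p = 0.00332), and 0 passed adjusted over the list alone. Msmo1, a sterol oxidase gene, was at 145.1 ± 13.8 TPM at day 8 and 69.8 ± 4.94 TPM at day 14 (n = 4, log2 fold change -1.04, limma adjusted p = 0.0831), higher in all 4 day 8 libraries. Fdft1 was at 29.4 ± 28.4 and 3.42 ± 0.882 TPM (n = 4, limma adjusted p = 0.131). The list's adjusted p was 0.303 with an estimated correlation, and without day 8 replicates 1 to 3 its median was -0.25 (camera adjusted p = 0.000267, and adjusted p = 0.651 with an estimated correlation). Its median was -1.06 with quantile normalization and -1.33 with aligned medians (camera adjusted p = 0.00306 and 0.00236). Glycolysis genes did not pass (median -0.22, mean 0.10, camera adjusted p = 0.106), with Hk3 at 6.07 ± 12.1 and 37.8 ± 6.29 TPM (SD, n = 4).

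Postnatally silenced growth genes fell as a list (median log2 fold change -4.32, 5 genes, camera adjusted p = 0.00309, 0.303 with an estimated correlation), and 5 passed adjusted over the list alone, 1 of them higher. That one, Igf2bp3, named after its values were seen, was at 0, 0, 0.00404 and 3.38 TPM at day 8 and 2.04 to 2.70 TPM at day 14. H19, an imprinted long RNA, was at 542.2, 21.6, 293.4 and 33.7 TPM at day 8 and 0.79 to 10.2 TPM at day 14 (log2 fold change -4.37, limma adjusted p = 0.0739). Fibroblast and muscle markers fell too (median -4.25, 9 genes, camera adjusted p = 3.01e-06, 0.423 with an estimated correlation), and 8 passed adjusted over the list alone, all lower. Col1a2 was at 361.4 ± 264.7 and 6.62 ± 2.28 TPM (SD, n = 4). Without day 8 replicates 1 to 3 the growth genes had a median of -0.35 (camera adjusted p = 0.0985), and the fibroblast and muscle markers turned to 1.19, higher at day 14 (camera adjusted p = 0.000343, and adjusted p = 0.651 with an estimated correlation). Endothelial markers did not pass (median -2.10, 3 genes, camera adjusted p = 0.167), with Cldn5 at 6648, 1339, 0 and 0.337 TPM at day 8 and Esam at 693.1, 66.8, 0.0512 and 0 TPM.

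The handling-sensitive lists did not pass camera in the planned comparison. Immediate-early genes had a median log2 fold change of 0.54 (18 genes, camera adjusted p = 0.289), with Ier3 at 1916 ± 702.4 and 4115 ± 472.8 TPM and Zfp36 at 7347 ± 2476 and 13519 ± 514.1 TPM (SD, n = 4). The mean of the immediate-early list was 9.69 to 10.27 in the day 8 libraries and 10.58 to 10.76 at day 14, without overlap. It was higher at day 14 by fry (adjusted p = 0.0402), with quantile normalization (median 0.56, camera adjusted p = 0.0185) and without day 8 replicates 1 to 3 (median 0.36, camera adjusted p = 0.013, adjusted p = 0.651 with an estimated correlation). With library medians aligned its median was -0.34 (camera adjusted p = 0.935). Heat shock and unfolded protein genes had a median of 0.19, and -0.69 with library medians aligned (15 genes, camera adjusted p = 0.364, camera direction lower), with Herpud1 at 491.4 ± 203.7 and 864.9 ± 52.2 TPM and Dnajb1 at 2160 ± 1241 and 555.8 ± 68.7 TPM. Dendritic cell markers had a median of 1.62, 0.27 with quantile normalization and 0.74 with aligned medians (6 genes, camera adjusted p = 0.289, fry adjusted p = 0.0412), with Clec10a at 0.0885, 0, 0 and 112.2 TPM at day 8 and Batf3 at 15.2 TPM in replicate 4 alone among the day 8 libraries. T cell markers had a median of 0.00, and -1.22 and -0.88 with quantile normalization and aligned medians (4 genes, camera adjusted p = 0.906), with Cd3d at 0.269 ± 0.427 and 2.78 ± 0.92 TPM and Cd3g at 13.5 ± 15.2 and 3.44 ± 0.321 TPM. NK cell and innate lymphoid markers had a median of 0.20, and -0.27 and -0.68 under the same scalings (3 genes, camera adjusted p = 0.952), with Il22 at 0, 25.8, 0 and 0.657 TPM at day 8 and 5.92 to 17.5 TPM at day 14 (log2 fold change 2.17, and 2.81 without day 8 replicates 1 to 3, limma adjusted p = 0.225 and 0.0702). Il2rb was at 0, 27.1, 0.144 and 1.71 TPM at day 8 and 1.57 to 5.38 TPM at day 14.

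Without day 8 replicates 1 to 3, day 8 replicate 4 alone stands against the 4 day 14 libraries and is assumed to vary as they do. In that fit, added after seeing the data, 91 genes passed, 88 higher and 3 lower at day 14, and 21 of them were among the 126. Of the 88, 35 had no read in day 8 replicate 4 and 40 were under 1 TPM there, and the median of their mean day 14 levels was 14.2 TPM. Cd209f (log2 fold change 2.24, SE 0.36, limma adjusted p = 0.0476) and Cirbp (-1.76, SE 0.26, limma adjusted p = 0.0414) passed in both. In that fit the log2 fold change was 3.93 for Retnlg, which had no read in day 8 replicate 4. It was 1.42 for Tfrc, 2.09 for Hars2, 1.79 for Castor1 and 1.76 for Chp2, each smaller than with all libraries and short of the threshold there. The other called genes named here were small RNAs. Of these, Mir132, Mir7688, Snord37 and Mir6992 rest on 2 to 15 reads per day 14 library, so their values there carry little weight. Csf1r was 0.90 higher, Adgre1 0.92, Cx3cr1 0.64 and C1qa 0.33 on the log2 scale, and none of these passed. Timd4 (-0.56) and H2-Ab1 (-0.38) changed sign. Leaving out day 8 replicate 4 instead gave 3254 genes, 2062 higher and 1192 lower, and all 126 were among them.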

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

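All tests of explanations in this part were chosen after the patterns were seen, but the 2 on further markers were fixed before the levels of those markers were seen. In 4 libraries, a library was taken as far from its group when its gap to the nearest other library, divided by the group's range, passed Dixon's critical value. Of 243 sets of 4 libraries, 52 did so. Chance gives about 1 in 20 for independent, normally spread sets. Many of these sets were genes named for a small p in the same data, and they moved together, so the number is no test of chance. Of the 52, 46 were at day 8, 44 of them with replicate 4 apart, and 6 were at day 14.

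At day 8 the ratio was 1.0, with replicate 4 high and the others at or near 0, for Cd209f, Snora28, Castor1, Chp2, Ms4a4c, Ccr2, Cd209g, Cd163, Runx3, Itgam, Mki67, Cdc6, Ifit1, Ccl8, Cd300lf, Spic, Hk3, Batf3, Timd4, Il10 and the eosinophil markers. Replicate 4 was also high with a ratio of 0.99 for Slamf6, Tlr2, Pdgfb and Cx3cr1, 0.98 for Itgal, Osm and Clec10a, 0.97 for Oasl2 and Tlr8, and 0.96 for Il1b. The ratio was 0.93 for Hars2, 0.92 for neutrophil markers, 0.88 for Ly6c2, 0.87 for the interferon response list and 0.85 for Cd3d. It was 0.84 for the share of TPM in the 10 highest genes, 32.3% in replicate 4 against 11.4 to 14.7% in the others. Replicate 4 was low for fibroblast and muscle markers (0.98), Ndn (0.97), Dcn (0.94), Col1a2 (0.88), Fam136a (0.87), Anxa1 (0.83) and Dnajb1 (0.83). Other day 8 libraries stood apart for Il22 (0.85, replicate 2 high) and lipid storage and efflux (0.86, replicate 3 low). At day 14, replicate 4 stood apart for Il1b (0.89, low), Clec10a (0.96, high) and B and plasma cell markers (0.89, low). Replicate 2 was low for Atp5c1 (0.92), replicate 3 high for Cd3d (0.94) and replicate 1 high for epithelial markers (0.83).

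Day 8 replicates 1 to 3 held few macrophage transcripts, with core gene means of 2.65, 3.93 and 2.34. Too few reads are argued against: thinned to 8237379 reads, the 5 other libraries each kept 24 of 24 core genes at 10 or more reads, against 9.9, 16 and 10.7. Thinning covers read depth only, not the number of cells or the amount of RNA that went in, which was not tested. Fibroblasts or muscle cells in place of macrophages may account for the pattern: of 22 further markers outside the fixed lists, 18 were higher in each of these 3 libraries than in the 5 others (1580 of 11969 genes with at least 1 TPM in any library, 13.2%), with Actg2 at 2317, 4369 and 3380 TPM and Mfap5 at 1987, 961.7 and 1061 TPM, and in the fixed list Lum at 7005, 3735 and 4359 TPM and Acta2 at 2851, 8455 and 5255 TPM. Endothelial markers (4.83, 3.82 and 0.01) and neuron and glia markers (3.13, 1.76 and 1.90) were also above day 8 replicate 4 (0.57 and 0.20), except endothelial markers in replicate 3, so other cells may be present too. The sort that would remove such cells is not described in the labels, and wrong labels stay open. Age was not tested, but day 8 replicate 4 was labelled with the same age and had a core gene mean of 7.77. Age alone therefore does not separate that library from replicates 1 to 3.

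In day 8 replicates 1 and 3, 69 and 62 of 95 genes of the core, resident, MHC class II, inflammatory and microbial sensing lists had at most 50 reads, of which 35 and 23 had any, while 23 and 29 had over 200. Reads or RNA carried over from the macrophage-rich libraries may account for the low values, the only ones tested. Over the genes with at most 50, reads followed those in day 8 replicate 4 and the day 14 libraries (Spearman's rho across genes 0.84 and 0.56, permutation p = 1e-05 each, the smallest that 100000 permutations can give, genes not being independent). The spread was 11.48 and 21.45 times that of Poisson counts, so a fixed share of carried reads is not the whole account. A few macrophages in the sample would give the same correlation and stay open.

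Day 14 replicate 1 stood apart for the fixed epithelial markers. Of 21 further markers outside the fixed lists, 17 had a read, and 15 of these were highest in that library (1032 of 11969 genes with at least 1 TPM in any library, 8.62%), which is consistent with epithelial cells in the sorted sample. Guca2a was at 222.5 TPM, Lypd8 at 106.6 TPM, Cldn3 at 153.3 TPM, Krt19 at 146 TPM and Cldn7 at 63.9 TPM there, while Muc2 and Slc26a3 were listed at 0 in every library. Which cells of the epithelium this would be, and whether the mouse differed, was not tested.

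For the count of 126 genes, 1 of the 35 splits into 4 and 4, the real one, gave as many, and the highest other split gave 0. This is the smallest share that 35 splits allow, so it cannot exclude chance in the assignment of libraries to ages. It says nothing of any single gene. Splits that part day 8 replicates 1 to 3 put unlike libraries in both groups, which widens the spread, so few calls could arise there. The count itself is fragile, at 0 when any of 6 single libraries is left out. The splits also do not separate age from other differences between the libraries.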

How the results depend on the processing

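The fit without day 8 replicates 1 to 3 and voom on recovered reads were chosen after seeing the data, and the other alternatives before. The main count was 126 genes, 125 higher and 1 lower. It was 57 (56 higher) with a pseudocount of 0.1, 44 (44 higher, 0 lower) with 5, 238 (236 higher, 2 lower) with no filter, 8 (8 higher, 0 lower) with a filter of TPM 5, 15 (15 higher, 0 lower) without the trend and 643 (506 higher, 137 lower) with array weights. The robust fit called 3 lower. With quantile normalization, median shift, voom and the exact permutation test it was 0 (0 higher, 0 lower), with 2144, 1035 and 2267 genes at an unadjusted p under 0.05 by limma for the first 3. The smallest exact p that 4 against 4 allows is 0.0286, which 1458 genes reached before adjustment. Leaving out 1 library gave 0 to 3254 genes, 0 to 2062 higher and 0 to 1192 lower. Day 8 and day 14 share replicate numbers, but same-numbered libraries did not deviate together (correlations 0.036, -0.062, -0.0014 and -0.011), and a replicate block gave 0 genes (0 higher, 0 lower, limma, 2316 unadjusted). Without day 8 replicates 1 to 3, 3 genes were lower and 5 lists were called, and with an estimated correlation 0 lists were. The resident list then had a median of 0.53 (camera adjusted p = 0.378) and 3.45 (0.423), and the monocyte list passed fry at 1.79 (fry adjusted p = 0.0402). Mitosis turned to -0.090 with a pseudocount of 5, -0.069 with a filter of TPM 5, -0.51 with quantile normalization and -0.63 with median shift. Il2rb turned to -0.18 with a pseudocount of 5, -1.19 with quantile normalization, -0.68 with median shift and -0.28 with array weights, and ran from -0.33 to 1.27 over the left-out libraries. Cd3g ran from -1.50 to 0.11 over them and was 0.0023 with voom. With quantile normalization Mki67 was -0.19, Abcg1 -0.46 and Cd3d -0.44. Without day 8 replicates 1 to 3, Plac8 was 0.15, Ctss -0.27, Ube2c 0.058, Mki67 -0.17, Dnajb1 0.48, Cd3g 0.64, Clec10a -0.026, Dcn 1.28, Col1a2 0.95, Cldn5 1.86, Esam 1.80, Timd4 -0.56 and H2-Ab1 -0.38. The cause of these turns was not tested, but median shift lowers every log2 fold change by the same amount, set mostly by day 8 replicate 3. Over the alternatives, the limma adjusted p of Cd209f ran from 1.25e-05 to 0.366 and that of Cirbp from 0.00133 to 0.366. Of 251 values of called named genes, 88 kept the call, 163 lost it and 0 reversed, and with quantile normalization 80.2% of the 126 genes kept their direction. Of the others, 25 reversed, 1429 kept their side and 107 became called. The planned count-based normalizations and count filters were not run, since they were meant for a table of counts and the deposited values are TPM. Voom scaled the recovered reads by library size only.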

Other observations

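All observations in this part were made after the data were seen, and the tests were chosen then. Without day 8 replicates 1 to 3, G0s2, which encodes a lipase inhibitor, had no read in day 8 replicate 4 and 24.7 to 37.5 TPM at day 14 (log2 fold change 4.95, SE 0.30, limma adjusted p = 0.00523). Sparc, a matrix protein gene, was at 23.9 TPM and at 94.2 to 142 TPM (log2 fold change 2.14, limma adjusted p = 0.0269). Msmo1 was lower at day 14 in that fit (-1.06, limma adjusted p = 0.0429), as was Rom1 (-2.01, limma adjusted p = 0.0485). A single day 8 library carries these values.

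Day 8 replicate 3 had high levels of chemokine and cytokine genes that were chosen after their values were seen. That library had the fewest genes with at least 10 reads after thinning (4708), so the values describe that library only. Ccl4 was at 19030 TPM, Ccl3 at 11730 TPM, Cxcl1 at 3993 TPM and Il6 at 690.9 TPM there. Ccl3 was at 0.486 TPM and 0 in day 8 replicates 1 and 2, and at 1350 TPM in replicate 4. In the same library Hdc, which makes histamine, was at 116.1 TPM and Ccr7 at 102 TPM.

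The 7 lists with fewer than 3 tested members were left out of camera and fry. By an exact two-sided permutation test of their means, adjusted over all 33 lists, none of the 33 passed: neutrophil, epithelial, and B and plasma cell markers had p = 0.0286, the smallest that 4 against 4 allows (adjusted p = 0.0555 each), eosinophil 0.114 (0.198), neuron and glia 0.143 (0.205), erythroid 0.429 (0.506) and mast cell markers 0.6 (0.66). Mean log2(TPM + 1) of neuron and glia markers was 3.13, 1.76, 1.90 and 0.20 at day 8 and 0.44 to 1.0 at day 14. Erythroid markers were at 0.62, 0.82, 0 and 0 at day 8 and 0 to 0.21 at day 14. Mast cell markers were at 0 to 0.62 at day 8 and 0.02 to 1.48 at day 14, where Tpsb2 was at 83.2 TPM in replicate 4. Neutrophil markers were at 0 to 0.24 and 0.56 to 0.70, with Retnlg the called member and Mpo, Elane and Ly6g listed at 0 throughout. Eosinophil markers were at 0 to 0.49 and 0.41 to 0.60, and B and plasma cell markers at 0.07 to 1.02 and 1.19 to 1.38. Epithelial markers were at 0.00 to 0.13 and 0.14 to 3.21.

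Xist, expressed from the inactive X chromosome, was at 13.01, 8.77 and 14.5 TPM in day 14 replicates 1, 3 and 4 and at most 0.016 TPM elsewhere. The Y-linked gene Ddx3y was at 11.2 and 8.18 TPM in day 8 replicates 1 and 4 and 11.6 TPM in day 14 replicate 2, and at most 0.01 TPM elsewhere. Day 8 replicates 2 and 3 had no read of either gene. The labels do not give the sex of the mice, and sex was not a term in the fits. Without day 8 replicates 1 to 3, a day 8 library with Ddx3y stands against day 14 libraries of which replicates 1, 3 and 4 had Xist. Age and sex cannot be fully told apart in that fit.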
